A study of Arabidopsis thaliana with 20 samples.

How the data were processed

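RNA was measured in 20 libraries of whole Arabidopsis thaliana rosettes, and the libraries fell into 6 groups by genotype and treatment. Group and replicate number came from the labels of each sample. Each library held a pool of 5 rosettes, per the labels' protocols, and the labels call the pools biological replicates. Libraries were made with the TruSeq RNA v2 kit, per the labels' protocols, a kit that does not mark the strand of the transcript. The deposited values were whole-number read counts per gene, not normalised, made by the authors with FastQC, TopHat2, SAMtools and HTSeq on TAIR10, per the submitters' processing notes. Versions, settings, the strand option and the treatment of reads that map to several places are not given in the sources used here. Reads from overlapping genes on opposite strands therefore could not be told apart, and members of multigene families such as glutathione S-transferases, cysteine-rich receptor-like kinases and the MAF genes could share reads.

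The files held 33602 genes, with 0 entries that named no gene, and 7167 genes were at 0 in every library. Symbols came from the RefSeq annotation of TAIR10.1, where 32835 loci (97.72%) matched, and coordinates are 1-based positions in that annotation. Totals ran from 20486137 to 20771667 counts per library, a spread of 1.38% of their mean. Totals this close are unusual for separate libraries, and no step that would equalise them is given in the sources used here. Low counts had the form of whole reads. Each count from 1 to 30 was taken by at least 49 genes, and genes with a mean count of 1 to 2 had a variance 1.175 times their mean. Depth therefore differed little between groups, and counting error was nearly the same in every library. Floors cover counting error only, whereas the p-values of edgeR and DESeq2 measure the spread between pools. Hypergeometric, Fisher and permutation p-values, and the interval of Fisher's odds ratio, take genes as units and measure no spread between pools. No library pair agreed within sampling noise, since chi-square per degree of freedom between libraries of a group ran from 6.74 to 72.37.

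Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes with too few counts were removed with filterByExpr on the 6 groups, which left 19954 genes, and library sizes were scaled with TMM factors. All 20 libraries entered 1 fit with the group means as coefficients, in order that groups of 3 shared the spread of all groups. The biological coefficient of variation was 17.2%. The 9 comparisons were ozone against control within each of 3 genotypes, each mutant against Col-0 without and with ozone, and the difference between the ozone response of each mutant and that of Col-0. Each was tested with edgeR's quasi-likelihood F-test, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with 0.05 as threshold. A called gene is one that passed. Log2 fold changes are given with their standard errors (SE), and levels in counts-per-million (CPM) with the standard deviation (SD) between libraries. Where every library of a group was at 0, the fold is a lower bound against a floor of 3 counts over the group. Where a group held 1 to 3 counts in all, levels are given without a fold.

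The tests, the lists and the rule for named genes were fixed before the data were examined. WRKY25, WRKY33 and WRKY75 were to be reported in every library. In each comparison the genes named were taken from the top of the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 5 CPM and no overlap between the libraries of the groups. In each list the called members with the largest changes, up to 4, were to be named, and then members without a call in order of change. The text leaves some of these out, such as WRKY31 under ozone in Col-0 (log2 fold change 6.53). Genes named outside this rule are said to be chosen after their values were seen.

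The 23 gene lists, with 408 members, were written from general knowledge of Arabidopsis and none was chosen on these samples. They covered the WRKY targets, other WRKY factors, regulators responsive to reactive oxygen species, glutathione S-transferases, antioxidant enzymes, the mitochondrial retrograde response, salicylic acid, jasmonate, ethylene, abscisic acid, tryptophan with camalexin and indole glucosinolates, pattern-triggered immunity, cysteine-rich receptor-like kinases, heat shock factors and chaperones, photosynthesis with chlorophyll synthesis, auxin, cell wall loosening, the cell cycle, senescence, phosphate starvation, the circadian clock, markers of flowers, seeds and root hairs, and reference genes. Of the members, 395 matched a symbol of the reference and 13 were kept with a symbol that the reference lacks. Lists were tested with camera of limma at its preset correlation of 0.01, beside camera with an estimated correlation and fry, and p-values were adjusted over the lists within each comparison. Counts of called members are given over all genes tested and adjusted over the list alone.

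Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, the replicate number as a block, only the libraries of the groups compared, Col-0 replicates 1 to 3 only, and leaving out each library in turn. A block of the replicate number within each treatment was added after the data were seen, because the numbers, taken from the sample labels, paired libraries within a treatment. Between each mutant and Col-0 the lowest correlation of same-numbered deviations from the group means was 0.207 and 0.101 in control, and 0.397 and 0.488 under ozone, for wrky25 wrky33 and wrky75 in turn.

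Overlaps of calls are set beside the overlap of independent lists, the product of both counts over the genes tested. Both mutants were compared with the same Col-0 libraries, so overlaps between them are also set beside 20 simulations of unchanged mutants and beside fits, added after the data were seen, in which each mutant had its own pair of Col-0 libraries.

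The test was checked on simulated counts for the real genes with 200 of them changed by known folds. In the simulation of ozone against control in Col-0, on 19768 genes, 33.3% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 96.9% of those changed 4-fold were called. For wrky25 wrky33 against Col-0 under ozone, on 19826 genes, the shares were 25.4%, 68.2% and 90.9%. In the difference of responses for that mutant the same folds gave 0%, 40.9% and 83.3% on 19826 genes. For wrky75 the difference of responses gave 9%, 46.2% and 75.8% on 19826 genes. Of edgeR's calls without a block, unchanged genes made up 2.4% (ozone response of wrky25 wrky33 minus Col-0) to 9.8% (wrky75 against Col-0 under ozone). Of DESeq2's calls, unchanged genes made up 10.5% (wrky25 wrky33 against Col-0 in control) to 19.8% (wrky75 against Col-0 in control). Camera found the changed list of 20 members and called 0 of 22 unchanged lists in simulated data of 19826 genes. The simulated genes varied independently of each other, so this check cannot show list calls that arise from correlation between genes.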

Results

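Transcript levels were measured by RNA sequencing in rosettes of Arabidopsis thaliana, 3 weeks old, that had been exposed to 350 ppb ozone for 2 h or kept without ozone. Ozone enters the leaf and gives rise to reactive oxygen species in the apoplast. The Columbia wild type (Col-0) had 4 control and 4 ozone libraries. The double mutant wrky25 wrky33 and the single mutant wrky75, which carry lesions in genes of WRKY transcription factors, had 3 control and 3 ozone libraries each. Every library held a pool of 5 rosettes. Total counts per library were 20539101 to 20636186 in Col-0 control, 20674728 to 20771667 in Col-0 ozone, and 20486137 to 20755838 in the mutant groups. Between 22214 and 22703 genes had a count in a library, and 19954 genes were tested. The 10 most abundant genes took 7.892% to 10.053% of the counts in control libraries and 4.745% to 5.986% in ozone libraries.

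Treatment separated all libraries on the first principal component, which held 84.6% of the variance. Control libraries lay between −111.9 and −81.9 on it and ozone libraries between 77.7 and 124. On the second component, with 2.6% of the variance, the wrky25 wrky33 ozone libraries lay between −33.8 and −20.3 and the wrky75 ozone libraries between 10.5 and 21.7. Col-0 ozone replicates 1 to 3 lay between 11 and 23 and replicate 4 at −20.9. Col-0 control replicate 4 lay at −25.9.

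**Figure D1:**
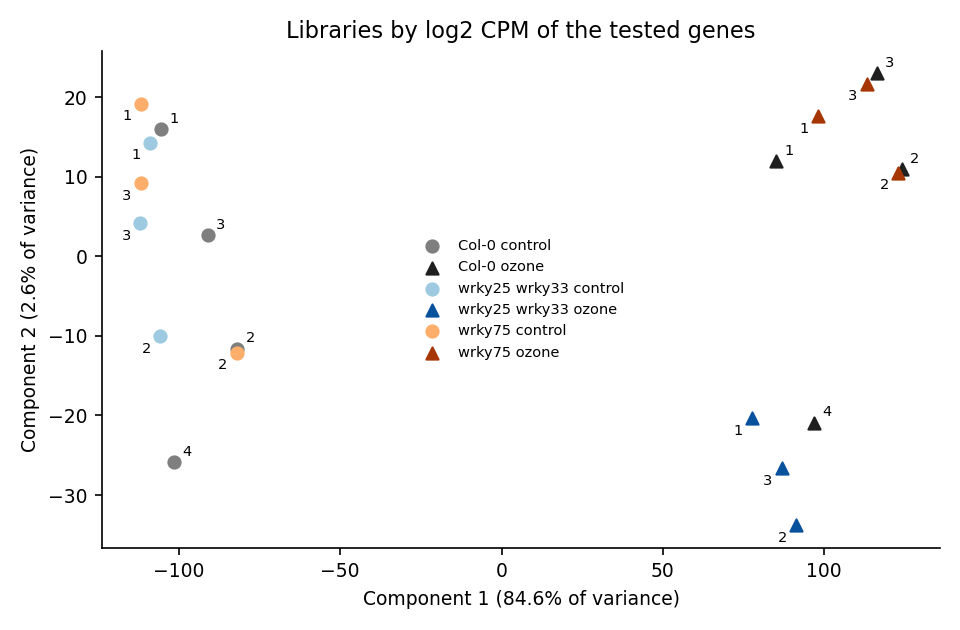
Principal components of log2 CPM of the 19954 genes tested, with the share of variance on each axis, circles for control and triangles for ozone libraries, and the replicate number beside each point. Component 1 parts all control libraries (−111.9 to −81.9) from all ozone libraries (77.7 to 124).

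The mutated genes were examined first in every library. WRKY25 (AT2G30250, chromosome 2, 12903236 to 12905198), WRKY33 (AT2G38470, chromosome 2, 16108361 to 16110766) and WRKY75 (AT5G13080, chromosome 5, 4149740 to 4151150) encode transcription factors of defence and stress responses. In Col-0 control libraries WRKY25 stood at 8.38, 16.09, 12.57 and 12.88 CPM, and in ozone libraries at 111.86, 128.44, 104.12 and 143.81 CPM. In libraries labelled wrky25 wrky33 it stood at 3.58, 5.55 and 3.14 CPM in control and at 176.15, 222.93 and 180.44 CPM under ozone. In libraries labelled wrky75 the levels of WRKY25 were 6.99, 14.46 and 6.94 CPM in control and 115.14, 154.61 and 123.68 CPM under ozone. WRKY33 was at 14.75, 23.78, 23.05 and 23.81 CPM in Col-0 control and 589.58, 436.96, 320.5 and 729.95 CPM in Col-0 ozone libraries. The double mutant had 12.57, 14.19 and 13.63 CPM of WRKY33 in control and 426.37, 343.82 and 223.77 CPM under ozone, and the single mutant had 11.97, 55.98 and 19.51 CPM and 570.21, 417.91 and 326.92 CPM. WRKY75 was at 0.35, 0.57, 0.73 and 0.27 CPM in Col-0 control and at 47.98, 128.54, 109.33 and 50.44 CPM in Col-0 ozone libraries. In libraries labelled wrky75 it reached 0.3, 0.43 and 0.35 CPM in control and 28, 72.78 and 56.04 CPM under ozone. In those labelled wrky25 wrky33 WRKY75 was at 0, 0 and 0.2 CPM in control and at 18.77, 25.44 and 20.8 CPM under ozone.

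**Figure D2:**
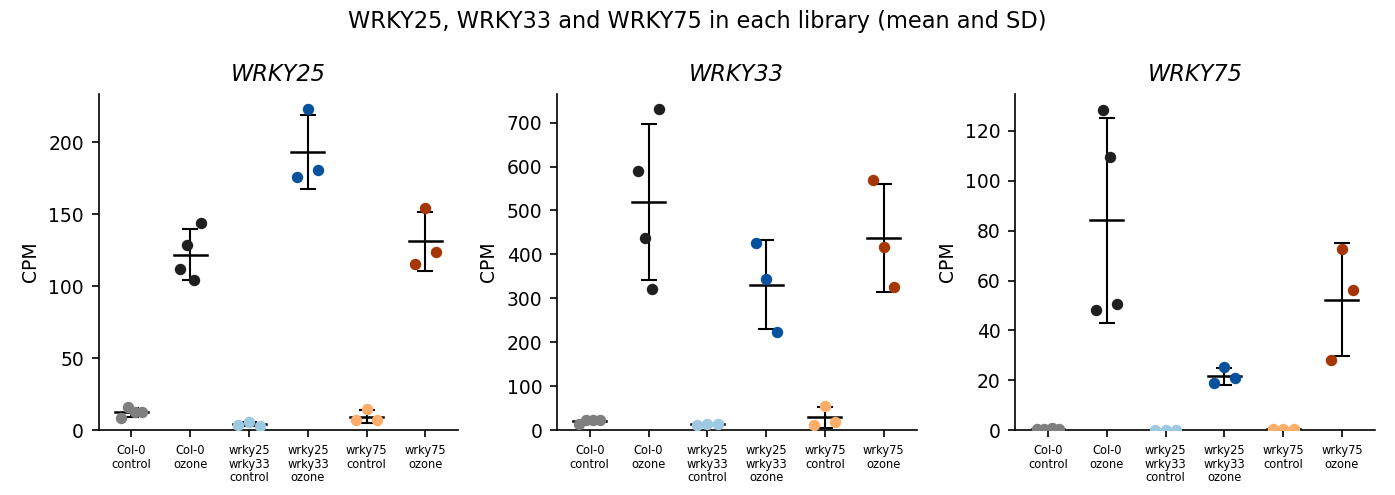
CPM of WRKY25, WRKY33 and WRKY75 in each library of the 6 groups, with points for libraries, horizontal lines for group means and bars for SD. All 3 transcripts were higher in every ozone library than in every control library, the libraries labelled as mutants of the same gene included.

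None of the mutants had lost the transcript of its own gene. Under ozone WRKY25 stood at 193.2 ± 25.9 CPM (SD, n = 3) in libraries labelled wrky25 wrky33 and at 122.1 ± 17.7 CPM (SD, n = 4) in Col-0, and its ozone response differed by a log2 fold change of 2.27 ± 0.36 (SE; adjusted p = 0.00454, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). In control the log2 difference of WRKY25 was −1.61 ± 0.28 (adjusted p = 0.0529, edgeR; 0.00153 with the replicate number as a block, and 2.41e-05 to 0.76 over the alternatives), and under ozone 0.66 ± 0.24 (adjusted p = 0.139, edgeR; 0.00319 with the block, and 3.14e-05 to 0.416 over the alternatives). For WRKY33 the log2 differences of the double mutant from Col-0 were −0.67 ± 0.41 in control and −0.65 ± 0.39 under ozone (adjusted p = 1 and 0.496, edgeR; 0.564 to 1 and 0.174 to 0.842 over the alternatives), and same-numbered libraries of the double mutant had 0.59 to 0.85 times and 0.7 to 0.79 times the level of Col-0. For WRKY75 the wrky75 libraries differed from Col-0 by −0.40 ± 0.79 in control and −0.69 ± 0.34 under ozone (adjusted p = 1 for both, edgeR; 0.279 under ozone with the block, and 0.0531 to 1 over the alternatives). In the 3 pairs of ozone libraries with the same number, wrky75 had 0.51 to 0.58 times the WRKY75 level of Col-0, so a lower level in its own mutant is not ruled out. The positions of the lesions are not given in the sources used here, and reads outside a disrupted part do not show whether a working protein is made. The counts thus do not check the genotype labels, and the mutant libraries are named by their labels throughout.

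Ozone changed most measured transcripts in Col-0. AT1G71520, an ethylene response factor of the AP2/ERF family, had no count in the 4 control libraries and 26 ± 10.7 CPM (SD, n = 4) under ozone, at least 720-fold higher against a floor of 3 counts over the group. PROPEP3 (AT5G64905), the precursor of a danger peptide, had 1 count in all control libraries together and 18.6 ± 6.60 CPM (SD, n = 4) under ozone. RHD2 (AT5G51060), an NADPH oxidase that forms superoxide, rose from 0.580 ± 0.246 to 364 ± 101 CPM (SD, n = 4), a log2 fold change of 9.29 ± 0.31 (SE). AT5G61160, an acyltransferase, rose from 0.533 ± 0.240 to 362.7 ± 74.8 CPM (9.40 ± 0.40), and DIN11 (AT3G49620), a dark-inducible dioxygenase, from 1.06 ± 0.941 to 653.5 ± 230.4 CPM (9.28 ± 0.63). PRE1 (AT5G39860), a helix-loop-helix protein that promotes cell elongation, fell from 10.15 ± 4.30 to 0.432 ± 0.209 CPM (log2 fold change −4.55 ± 0.37), and EXPA8 (AT2G40610), an expansin, from 77.6 ± 31.1 to 3.52 ± 1.82 CPM (−4.47 ± 0.37). AT1G29430, of the auxin-responsive SAUR family, fell by 4.22 ± 0.25 on the log2 scale. AT2G27420, a cysteine proteinase, fell by 4.08 ± 0.74 and AT4G29905 by 4.02 ± 0.28.

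In Col-0, 13907 genes were called, 69.7% of those tested, with 6635 higher and 7272 lower under ozone (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 3569 rose and 2827 fell by at least 2-fold. Adjusted p was 1.02e-13 for RHD2 and 4.52e-09 for PRE1. The median log2 fold change of all genes was −0.08. With upper-quartile factors the median moved to −0.281 and 5436 genes were higher and 9176 lower, so that 37.2% rather than 47.7% of the calls were higher.

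Transcription factors of stress signalling rose together. Of 26 other WRKY factors measured, 23 rose over all genes tested and 23 adjusted over the list alone, among them WRKY40 (log2 fold change 7.58 ± 0.53), WRKY30 (6.06 ± 0.66) and WRKY6 (5.04 ± 0.23). All 3 targets rose, WRKY25 by 3.29 ± 0.25, WRKY33 by 4.60 ± 0.42 and WRKY75 by 7.43 ± 0.47. All 20 regulators responsive to reactive oxygen species rose, by either adjustment, with OXI1, a kinase activated by oxidative bursts, at 7.79 ± 0.24, the calmodulin-like CML37 at 7.62 ± 0.49 and the zinc finger factors ZAT12 and ZAT11 at 7.18 ± 0.60 and 7.18 ± 0.59. Camera gave adjusted p = 8.61e-08 for the other WRKY factors, 2.15e-08 for the regulators and 0.00608 for the targets. With an estimated correlation adjusted p = 0.0986 for each of the 3 lists, and in none of the ozone comparisons did a list call hold with an estimated correlation. Fry, which does not compare a list with other genes, also called, in the same direction, the 16 lists that camera called in each ozone comparison.

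Detoxification and mitochondrial stress genes rose as well. Of 26 glutathione S-transferases, which conjugate oxidised compounds, 21 rose and 4 fell, over all genes and adjusted over the list alone, led by GSTU4 (7.48 ± 0.55), GSTF3 (7.24 ± 0.33) and GSTU3 (7.14 ± 0.55). In the mitochondrial retrograde response 8 of 9 members rose, including the alternative oxidase AOX1D (7.06 ± 0.50), BCS1 (4.49 ± 0.36), the glucosyltransferase UGT74E2 (4.23 ± 0.27) and the dehydrogenase NDB2 (4.19 ± 0.24), with the same count adjusted over the list alone. Camera gave adjusted p = 6.35e-07 and 4.66e-05 for these lists, and adjusted p = 0.0986 with an estimated correlation for both. Antioxidant enzymes went both ways, with 8 of 16 higher and 5 lower by either adjustment (camera adjusted p = 0.157). GSH2 of glutathione synthesis rose by 3.13 ± 0.11, DHAR2 by 2.1 ± 0.21 and the ascorbate peroxidase APX1 by 1.72 ± 0.13, whereas the photorespiratory catalase CAT2 fell by 1.94 ± 0.34. In the list of heat shock factors and chaperones 15 of 17 members rose and 1 fell by either adjustment, with HSP90.1 at 6.70 ± 0.36, HSFA2 at 6.29 ± 0.24, AT1G07400 at 5.67 ± 0.37 and HSP70 at 5.07 ± 0.25 (camera adjusted p = 1.6e-05; adjusted p = 0.129 with an estimated correlation).

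Most measured members of 3 lists of immunity rose. All 24 genes of pattern-triggered immunity rose by either adjustment, such as NHL10 (7.73 ± 0.38) and the syntaxin SYP122 (6.11 ± 0.44), with camera adjusted p = 1.5e-11 and adjusted p = 0.0986 with an estimated correlation. Of 22 cysteine-rich receptor-like kinases 19 rose and 2 fell by either adjustment, with CRK20 at 6.73 ± 0.29, CRK13 at 5.48 ± 0.38, CRK11 at 5.42 ± 0.28 and CRK36 at 4.51 ± 0.39 (camera adjusted p = 2.28e-06; adjusted p = 0.129 with an estimated correlation). In tryptophan, camalexin and indole glucosinolate synthesis 16 of 20 members rose and 2 fell by either adjustment. PAD3, the last enzyme of camalexin synthesis, rose by 8.68 ± 0.51, CYP71A12 by 8.44 ± 0.25 and the methyltransferase IGMT2 by 7.37 ± 0.53 (camera adjusted p = 1.72e-06; adjusted p = 0.108 with an estimated correlation).

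Hormone pathways differed in direction. Of 19 salicylic acid genes 17 rose, and 18 adjusted over the list alone, with GRX480 at 5.89 ± 0.64, FMO1 at 5.27 ± 0.68, EDS5 at 4.76 ± 0.42 and PBS3 at 4.51 ± 0.49. The late markers PR2 (1.29 ± 0.60, adjusted p = 0.0644, edgeR) and PR1 (−0.34 ± 0.84, adjusted p = 0.73, edgeR) did not pass. Of 26 jasmonate genes 17 rose by either adjustment, with AOC3 at 6.12 ± 0.39, JAZ1 at 5.02 ± 0.50, JAZ8 at 4.89 ± 0.48 and LOX4 at 4.67 ± 0.33. In ethylene synthesis and response 15 of 19 rose and 1 fell, and 16 rose and 1 fell adjusted over the list alone. ORA59 stood at 6.49 ± 0.37, ERF1 at 5.37 ± 0.20, ERF2 at 5.09 ± 0.41 and the ACC synthase ACS2 at 4.80 ± 0.50. Camera gave adjusted p = 3.15e-06, 0.00013 and 0.000119 for these 3 lists, and adjusted p = 0.25, 0.404 and 0.183 with an estimated correlation. Abscisic acid genes split, with 10 of 20 higher and 7 lower by either adjustment (camera adjusted p = 0.626). The receptors PYL6 (5.44 ± 0.51), PYL5 (3.79 ± 0.46) and PYL4 (2.21 ± 0.25) and the catabolic enzyme CYP707A3 (2.47 ± 0.67) rose. Auxin genes went down, with 15 of 19 lower and 1 higher by either adjustment, including IAA6 (−4.59 ± 0.51), IAA29 (−3.97 ± 0.48), IAA14 (−3.75 ± 0.30) and IAA5 (−3.62 ± 0.37), with camera adjusted p = 1.8e-05 and adjusted p = 0.0986 with an estimated correlation.

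Genes of photosynthesis and most genes of cell wall loosening fell. All 27 genes of photosynthesis and chlorophyll synthesis were lower by either adjustment, with a median log2 fold change of −1.2. GUN4 fell by 2.40 ± 0.24, CAO by 2.21 ± 0.19, HEMA1 by 1.85 ± 0.25 and CHLH by 1.74 ± 0.24 (camera adjusted p = 2.69e-06; adjusted p = 0.404 with an estimated correlation). Of 13 genes of cell wall loosening 11 fell by either adjustment, among them the expansins EXPA11 (−2.53 ± 0.30), EXPA5 (−2.01 ± 0.17) and EXPA6 (−1.86 ± 0.15), with camera adjusted p = 0.000272 and adjusted p = 0.129 with an estimated correlation. In the cell cycle list 4 of 17 fell by either adjustment, CYCD3;1 by 0.89 ± 0.12 and PCNA1 by 0.68 ± 0.20 (camera adjusted p = 0.407). Senescence genes rose in 6 of 10 members by either adjustment, with SAG21 at 5.59 ± 0.55, NAC055 at 4.76 ± 0.75, SAG13 at 3.60 ± 0.56 and SEN1 at 3.05 ± 0.46 (camera adjusted p = 0.0382; adjusted p = 0.404 with an estimated correlation).

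The remaining lists gave no call with camera. Among 14 phosphate starvation genes 6 rose and 4 fell by either adjustment, with SPX1 at 1.74 ± 0.23 and the transporter PHT1;4 at 1.65 ± 0.31 (camera adjusted p = 0.744). In the circadian clock list 3 of 9 rose and 4 fell by either adjustment, with LUX at 2.86 ± 0.24, PRR5 at 1.83 ± 0.64, CCA1 at −1.59 ± 0.24 and TOC1 at 1.53 ± 0.09. Its median of −0.11 and its mean of 0.19 differed in sign, and the test pointed up (camera adjusted p = 0.925). Of 15 markers of flowers, seeds and root hairs 2 were measured. The floral factor AG fell by 1.86 ± 0.32, and PYK10 stood at −0.41 ± 0.31 without passing (edgeR adjusted p = 0.248). The 8 reference genes were not constant. By either adjustment 5 rose, with UBQ10 at 2.03 ± 0.16 and ACT8 at 0.64 ± 0.16, and 1 fell, and with upper-quartile factors 3 rose and 2 fell.

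**Figure D3:**
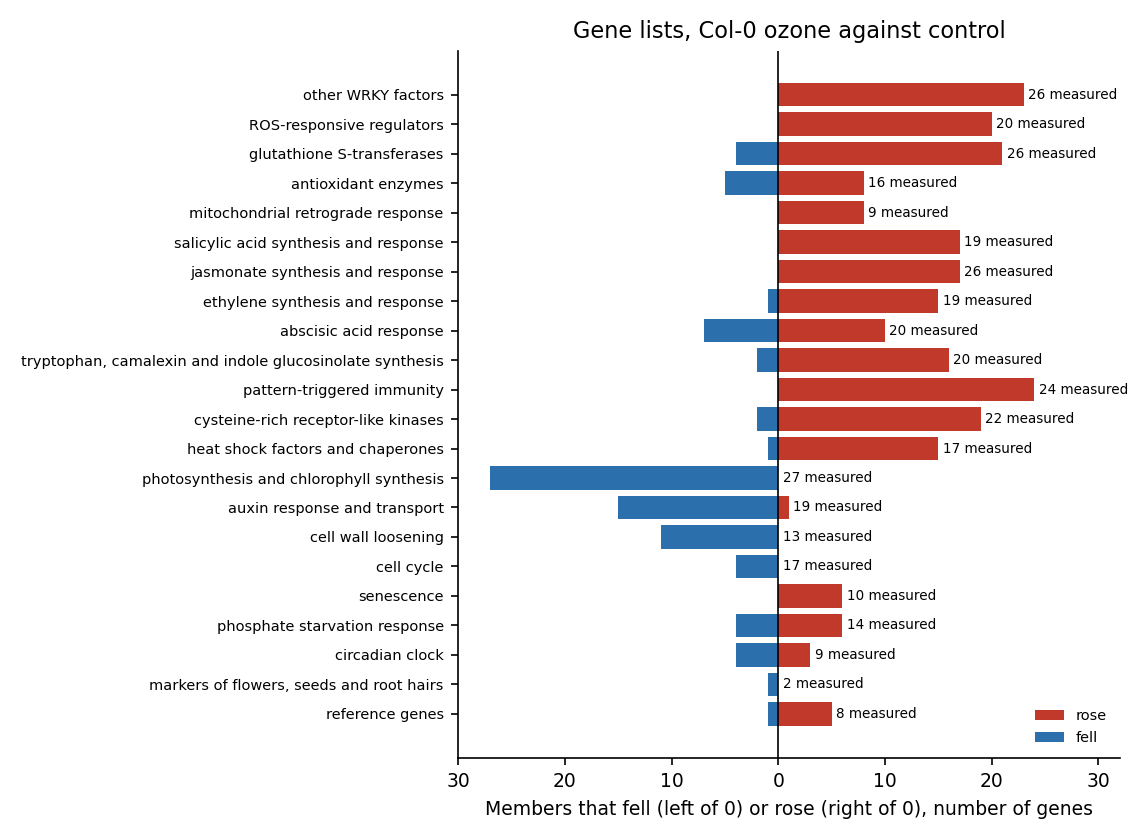
Number of genes in each of 22 lists that rose (right of 0) or fell (left of 0) under ozone in Col-0 at an adjusted p under 0.05, with the number measured beside each bar. All 24 pattern-triggered immunity genes rose and all 27 photosynthesis and chlorophyll genes fell.

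The same question was asked of the mutants. In libraries labelled wrky25 wrky33 ozone raised AT1G71520 from no count in 3 control libraries to a level at least 301-fold above the floor, and CRK31, a cysteine-rich receptor-like kinase, from no count to 14.9 ± 3.72 CPM (SD, n = 3), at least 297-fold. SUC7, of the sucrose transporter family, had 2 counts in all control libraries together and 59.3 ± 11.1 CPM (SD, n = 3) under ozone. AT5G61160 rose by 10.28 ± 0.49 on the log2 scale and AT1G56060, a small transmembrane protein, by 9.59 ± 0.60. The largest decreases were AT2G27420 (−4.71 ± 0.90), EXPA8 (−4.40 ± 0.42), AT1G29430 (−4.35 ± 0.29), AT1G13650 (−3.93 ± 0.85) and the factor BZIP34 (−3.82 ± 0.28). WRKY25 rose by 5.56 ± 0.32, WRKY33 by 4.62 ± 0.48 and WRKY75 by 8.22 ± 0.72. Ozone changed 12980 genes in these libraries, 6207 higher and 6773 lower (edgeR quasi-likelihood test, adjusted p under 0.05), of which 3534 rose and 2674 fell at least 2-fold. With upper-quartile factors 37.6% rather than 47.8% of the calls were higher.

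The lists moved as follows in wrky25 wrky33-labelled libraries, with counts over all genes. All 20 regulators responsive to reactive oxygen species rose, as did 24 of 26 other WRKY factors, 23 of 24 genes of pattern-triggered immunity, 18 of 19 of salicylic acid, 18 of 26 of jasmonate and 13 of 19 of ethylene. All 9 genes of the mitochondrial retrograde response, 21 of 26 glutathione S-transferases, 20 of 22 cysteine-rich receptor-like kinases, 13 of 17 heat shock genes, 16 of 20 genes of tryptophan and camalexin synthesis and 7 of 10 senescence genes rose too. Members fell in photosynthesis (26 of 27), auxin (15 of 19) and cell wall loosening (11 of 13). Adjusted over the list alone, the counts differed in ethylene, with 14 higher, and in photosynthesis, with 27 lower. Camera called 16 lists, with adjusted p of 5.65e-11 for pattern-triggered immunity and 2.13e-08 for the regulators. With an estimated correlation adjusted p = 0.0825 for the lowest and adjusted p = 0.4 for the highest of the 16.

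In libraries labelled wrky75 ozone raised AT5G59530, an oxygenase of the 2-oxoglutarate family, from no count to 14.1 ± 3.61 CPM (SD, n = 3), at least 285-fold above the floor. The glucosyltransferase UGT73B4 rose from 0.0982 ± 0.0467 to 154.6 ± 40.4 CPM (SD, n = 3), a log2 fold change of 10.52 ± 0.56 (SE), and AT1G56060 rose by 9.79 ± 0.59. AT1G59950, of the aldo-keto reductase family, and the cytochrome P450 CYP82C3 had 1 and 2 counts in the control libraries together and 27.2 ± 8.39 and 43.8 ± 12.2 CPM (SD, n = 3) under ozone. AT1G29430 fell by 5.04 ± 0.31, EXPA8 by 4.89 ± 0.43, AT5G54585 by 4.79 ± 0.50, AT2G29300 by 4.68 ± 0.58 and AT1G13650 by 4.51 ± 0.87. WRKY25 rose by 3.79 ± 0.29, WRKY33 by 3.91 ± 0.46 and WRKY75, the gene named in the label, by 7.15 ± 0.56. Ozone changed 13594 genes here, 6390 higher and 7204 lower (edgeR quasi-likelihood test, adjusted p under 0.05), of which 3744 rose and 3322 fell at least 2-fold. With upper-quartile factors 38% rather than 47% of the calls were higher. Among the lists, 23 of 26 other WRKY factors, 19 of 20 regulators responsive to reactive oxygen species, 23 of 24 genes of pattern-triggered immunity, 15 of 20 of tryptophan and camalexin synthesis and 16 of 26 of jasmonate rose, and all 27 photosynthesis genes fell, with the same counts adjusted over the list alone. Camera called 16 lists, and with an estimated correlation adjusted p = 0.105 for the lowest and adjusted p = 0.41 for the highest of them.

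Genes called in Col-0 were for the most part called in the mutants as well. Of the 6635 genes higher in Col-0, 5675 (85.5%) were also higher in wrky25 wrky33 and 6049 (91.2%) in wrky75, where independent lists would share 2064 and 2125. Of the 7272 lower genes, 6161 (84.7%) and 6617 (91%) were shared, against 2468 and 2625. All 3 genotypes shared 5445 higher and 5969 lower genes. The 3 comparisons have no control libraries in common. In opposite directions, 26 genes were called between Col-0 and wrky25 wrky33 and 0 between Col-0 and wrky75 (edgeR). For the 6396 genes with an at least 2-fold change in Col-0, the median ratio of the mutant to the Col-0 log2 response was 0.952 in wrky25 wrky33 and 1.055 in wrky75. Across these genes, which are not independent replicates, Pearson's r was 0.957 and 0.981 and Spearman's rho 0.954 and 0.975.

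Without ozone the rosettes labelled wrky25 wrky33 differed from Col-0 in a handful of genes, and 2 of them lie beside the mutated loci. ATCHX13 (AT2G30240, chromosome 2, 12899907 to 12902779), a cation/H+ exchanger gene downstream of WRKY25 on the same strand, had no count in Col-0 control and 14.1 ± 2.25 CPM (SD, n = 3) in the double mutant, at least 390-fold higher. AT2G38480 (chromosome 2, 16110741 to 16111797), whose 3′ end overlaps that of WRKY33 on the opposite strand, stood at 14.4 ± 0.444 CPM against 7.49 ± 0.845 CPM in Col-0 (SD, n = 3 and 4; log2 fold change 0.94 ± 0.14). AT5G35935 (chromosome 5, 14083388 to 14089891), annotated as a pseudogene, was higher, 15.8 ± 1.10 against 3.18 ± 1.16 CPM (2.31 ± 0.34). The retroposon SADHU3-2 (AT3G42658, chromosome 3, 14749400 to 14750294) was lower, 0.333 ± 0.207 against 6.59 ± 2.94 CPM (−4.28 ± 0.71). AT1G74290 (chromosome 1, 27931836 to 27934268), of the alpha/beta-hydrolase family, was also lower, 0.685 ± 0.203 against 3.18 ± 0.318 CPM (−2.21 ± 0.32). ATCHX13, SADHU3-2 and AT1G74290 fell outside the rule for named genes and were chosen after their values were seen. Without strand information, reads in the overlap of AT2G38480 and WRKY33 (16110741 to 16110766) could not be assigned to either gene.

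These 5 genes, 3 higher and 2 lower, were the calls in control (edgeR quasi-likelihood test, adjusted p = 7.79e-08 for ATCHX13, 0.0116 for AT2G38480, AT5G35935 and AT1G74290, and 0.0408 for SADHU3-2). Without replicate 1, 2 or 3 of wrky25 wrky33 control the count was 1, and without Col-0 control replicate 3 or 4 it was 3. Only the compared groups gave 1 call and DESeq2 16. With the replicate number as a block within each treatment 53 genes were called, 6 higher and 47 lower. All 5 calls lay outside the 23 lists when adjusted over all genes. Adjusted over the list alone, 2 of the 3 targets were lower, as were 3 glutathione S-transferases, 3 cysteine-rich receptor-like kinases, 2 genes of tryptophan and camalexin synthesis and 1 senescence gene, and 1 heat shock gene was higher. Camera called 18 lists, such as the cysteine-rich receptor-like kinases (adjusted p = 3.82e-12; adjusted p = 0.1 with an estimated correlation), the glutathione S-transferases (1.22e-06; adjusted p = 0.102 with an estimated correlation) and the salicylic acid list (4.84e-07; adjusted p = 0.399 with an estimated correlation). Of the 18, the targets alone held, with camera adjusted p = 2.25e-08 and adjusted p = 0.00326 with an estimated correlation. That list has 3 genes, and 2 of them, WRKY25 and WRKY33, are named in the label. Its result is therefore not independent of the genotypes compared, and a correlation estimated on so few genes is uncertain.

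In control the rosettes labelled wrky75 also differed from Col-0 in few genes. AT3G30122 (chromosome 3, 11758491 to 11760858), a transcribed pseudogene, was higher, 5.01 ± 0.222 against 1.5 ± 0.286 CPM (SD, n = 3 and 4; log2 fold change 1.74 ± 0.19). MAF4 (AT5G65070, chromosome 5, 25992243 to 25996174), a MADS-box repressor of flowering, stood at 7.33 ± 0.975 against 1.04 ± 0.124 CPM (2.82 ± 0.38). MRD1 (AT1G53480, chromosome 1, 19963047 to 19964712) had 134 counts in the 3 wrky75 libraries, a mean of 2.21 ± 0.302 CPM, and 2 counts in the 4 Col-0 libraries. AT5G35935 was lower, 0.0990 ± 0.0504 against 3.18 ± 1.16 CPM (−4.92 ± 0.65), and so was SADHU3-2, 0.116 ± 0.0305 against 6.59 ± 2.94 CPM (−5.77 ± 0.83). MAF5 (AT5G65080, chromosome 5, 25997504 to 26002465), next to MAF4 and a paralogue of it, was at 14.9 ± 1.31 against 0.721 ± 0.271 CPM without passing. The fit takes the spread of a gene from all groups. In wrky25 wrky33-labelled control libraries MAF5 stood at 4.50 ± 5.35 CPM (SD, n = 3), and whether this spread kept it from passing was not tested. MRD1, AT3G30122, MAF4, MAF5 and SADHU3-2 were chosen after their values were seen.

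The 5 calls, 3 higher and 2 lower, had adjusted p of 0.000335 for MRD1 and AT3G30122, 0.00308 for MAF4 and AT5G35935 and 0.00752 for SADHU3-2 in edgeR's quasi-likelihood test, and 0.0707 for MAF5 (0.000829 to 0.672 over the alternatives). Without wrky75 control replicate 2 there were 3 calls, without replicate 1 there were 64, and DESeq2 called 19. All 5 lay outside the 23 lists. Camera called 8 lists, such as the cysteine-rich receptor-like kinases as lower (adjusted p = 2.71e-06) and the cell cycle as higher (adjusted p = 0.000327). With an estimated correlation adjusted p = 0.813 for all 8.

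Under ozone, some genes of camalexin synthesis and of immunity were lower in rosettes labelled wrky25 wrky33 than in Col-0. CYP71A13 (AT2G30770), which makes indole-3-acetonitrile for camalexin, stood at 22.8 ± 11.4 CPM (SD, n = 3) in the double mutant and 653.3 ± 321.5 CPM (SD, n = 4) in Col-0, a log2 difference of −4.84 ± 0.65 (SE), and PAD3 (AT3G26830) at 361.7 ± 78.7 against 1772 ± 266.6 CPM (−2.29 ± 0.42). AT1G26390, a berberine bridge enzyme-like oxidase, stood at 1.98 ± 0.810 against 61.7 ± 37.3 CPM (−4.96 ± 0.62), and BGLU45 (AT1G61810), a monolignol glucosidase, at 3.5 ± 0.609 against 79.9 ± 34.3 CPM (−4.51 ± 0.31). CYP82C3 (−4.17 ± 0.34) and NRT2.6 (−4.10 ± 0.39), of the nitrate transporter family, were lower too. In control CYP71A13 stood at 0.546, 0.3 and 0.912 CPM in the double mutant and 4.817, 7.64, 4.893 and 1.411 CPM in Col-0. PAD3 stood there at 0.447, 0.75 and 0.962 CPM and at 5.77, 5.396, 4.453 and 1.639 CPM in turn. Both were thus lower without ozone too, without a call, and neither had a passing difference of ozone response. Other genes were higher under ozone. AT2G38480, beside WRKY33, was at 14.3 ± 2.46 against 2.59 ± 0.512 CPM (2.46 ± 0.15), CML41 (AT3G50770), a calmodulin-like protein, at 58.9 ± 8.05 against 14.5 ± 2.77 CPM (2.02 ± 0.30), the B-box factor BBX17 at 6.95 ± 1.73 against 1.69 ± 1.02 CPM (2.05 ± 0.38), and the glucanase BG3 differed by 1.99 ± 0.55.

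**Figure D4:**
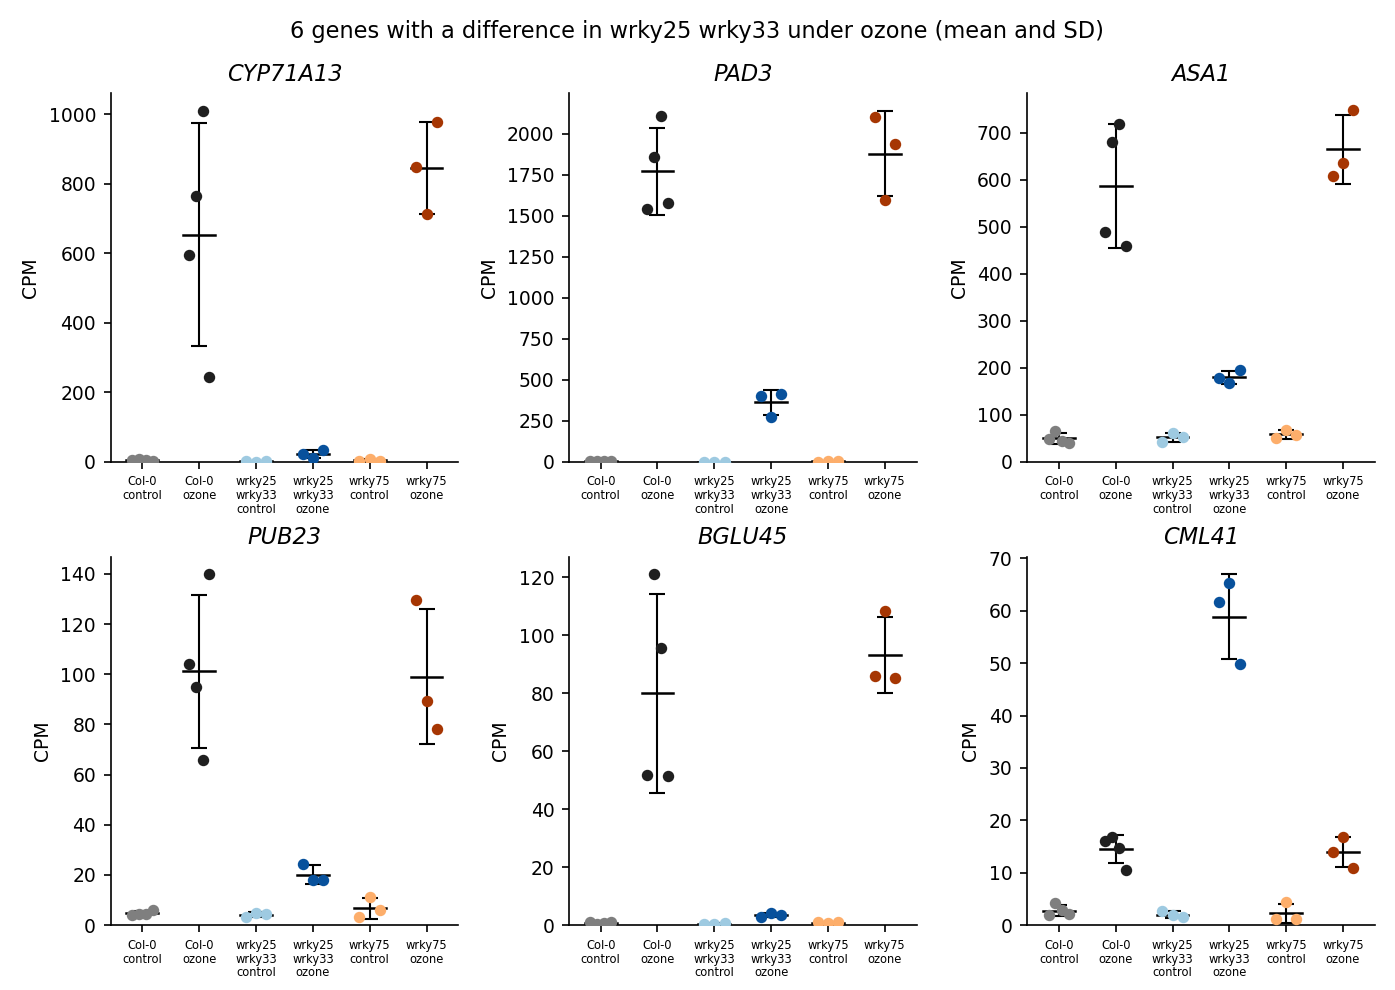
CPM of CYP71A13, PAD3, ASA1, PUB23, BGLU45 and CML41 in each library of the 6 groups, with points for libraries, horizontal lines for group means and bars for SD. Under ozone PAD3 averaged 361.7 CPM in wrky25 wrky33-labelled libraries, 1772 in Col-0 and 1880 in wrky75-labelled libraries.

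Of the genes tested under ozone, 1064 (5.3%) were called, 311 higher and 753 lower in wrky25 wrky33-labelled libraries (edgeR quasi-likelihood test, Benjamini-Hochberg), and 79 and 313 of them differed at least 2-fold. With the replicate number as a block 2394 genes were called, 1084 higher and 1310 lower, 1063 of them shared, and with the block within each treatment 2444 were higher and 2228 lower, so the excess of lower genes depended on the model. Adjusted p was 0.000143 for CYP71A13, 0.00227 for PAD3, 5.85e-08 for BGLU45, 1.43e-08 for AT2G38480 and 0.0406 for BG3. Of the 753 lower genes, 691 had risen with ozone in Col-0, and of the 311 higher genes 145 had fallen and 104 had risen. Only the compared groups gave 707 calls. Without wrky25 wrky33 ozone replicate 3 the count was 583, and without replicate 2 it was 673.

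The lower genes under ozone were spread over several lists. In tryptophan, camalexin and indole glucosinolate synthesis 8 of 20 members were lower, and 13 lower and 1 higher adjusted over the list alone, with the regulator MYB122 at −1.81 ± 0.21 and the anthranilate synthase ASA1 at −1.71 ± 0.20 beside CYP71A13 and PAD3. The list had adjusted p = 8.07e-11 with camera, adjusted p = 0.166 with an estimated correlation and 0.000636 with fry. In pattern-triggered immunity 7 of 24 were lower and 10 adjusted over the list alone, with PROPEP3 at −2.57 ± 0.35, the ubiquitin ligase PUB23 at −2.33 ± 0.32, PROPEP2 at −1.44 ± 0.36 and the Pep receptor PEPR2 at −1.21 ± 0.22 (camera adjusted p = 8e-06; adjusted p = 0.51 with an estimated correlation). Of 26 glutathione S-transferases 6 were lower, and 6 lower and 4 higher adjusted over the list alone, with GSTU3, GSTU9, GSTU11 and GSTU10 at −2.86 ± 0.43, −2.76 ± 0.40, −2.61 ± 0.40 and −2.52 ± 0.21 (camera adjusted p = 0.0454; adjusted p = 0.649 with an estimated correlation). In the list of regulators responsive to reactive oxygen species 4 of 20 were lower, and 6 lower and 1 higher adjusted over the list alone, with ERF5 at −1.94 ± 0.52, ERF6 at −1.72 ± 0.41, OXI1 at −0.67 ± 0.16 and the NADPH oxidase RBOHF at −0.46 ± 0.10 (camera adjusted p = 0.0454; adjusted p = 0.649 with an estimated correlation). Of 26 jasmonate genes 2 were lower and 4 adjusted over the list alone, JAZ5 at −1.14 ± 0.31 and ACX1 at −0.92 ± 0.21 (camera adjusted p = 0.00433; adjusted p = 0.649 with an estimated correlation).

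Lists without a camera call also held lower genes under ozone. Of 19 ethylene genes 6 were lower, and 7 lower and 1 higher adjusted over the list alone, including the ethylene synthesis genes ACS2 (−1.85 ± 0.42), ACS6 (−1.73 ± 0.49) and ACO4 (−1.19 ± 0.18) and the factor ORA59 (−1.24 ± 0.28). Among 26 other WRKY factors 4 were lower and 6 adjusted over the list alone, with WRKY30 at −2.21 ± 0.57, WRKY55 at −2.14 ± 0.42, WRKY6 at −0.94 ± 0.21 and WRKY15 at −0.65 ± 0.17. WRKY75 itself was lower in wrky25 wrky33-labelled libraries, 21.7 ± 3.4 against 84.1 ± 41 CPM (−1.96 ± 0.36, adjusted p = 0.00225, edgeR). Among 22 cysteine-rich receptor-like kinases 4 were lower, and 7 lower and 1 higher adjusted over the list alone, such as CRK20 (−1.96 ± 0.22) and CRK22 (−1.15 ± 0.15). ALD1 of pipecolic acid synthesis was the lower member of the salicylic acid list (−2.48 ± 0.62). In the abscisic acid list PYL6 (−1.69 ± 0.41) and ABI2 (−0.51 ± 0.14) were lower, and among antioxidant enzymes VTC5 (−0.72 ± 0.18) and GSH2 (−0.42 ± 0.11). With RLE factors 1 abscisic acid gene was lower. In the mitochondrial retrograde list 2 of 9 were higher, UGT74E2 by 1.30 ± 0.20 and SOT12 by 0.84 ± 0.12, and 2 were higher and 3 lower adjusted over the list alone. Heat shock genes had 2 higher members, HSP17.6II (1.18 ± 0.33) and HSP23.6-MITO (1.13 ± 0.27), and 1 lower, whereas with DESeq2 1 was higher and 1 lower. EXPA16 (0.86 ± 0.22) and the clock gene PRR9 (0.84 ± 0.16) were higher as well.

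Rosettes labelled wrky75 differed from Col-0 under ozone in few genes, and most of them were those of the control comparison. HEI10 (AT1G53490, chromosome 1, 19963267 to 19966952), a meiotic crossover factor, was higher, 9.77 ± 2.23 against 1.42 ± 0.150 CPM (SD, n = 3 and 4; log2 fold change 2.77 ± 0.19). MRD1, which overlaps HEI10 on the opposite strand so that their reads could not be told apart, had 192 counts against 6 in Col-0. AT3G30122 was at 1.96 ± 0.0989 against 0.574 ± 0.128 CPM (1.76 ± 0.23) and MAF4 at 5.28 ± 0.408 against 0.704 ± 0.173 CPM (2.89 ± 0.40). AT5G35935 had 2 counts in the wrky75 libraries, where Col-0 had 3.69 ± 2.37 CPM (SD, n = 4). MAF5 was at 13.9 ± 1.09 against 0.500 ± 0.227 CPM without passing. In wrky25 wrky33-labelled ozone libraries, which entered the same fit, MAF5 stood at 2.95 ± 4.09 CPM (SD, n = 3). HEI10, MRD1, AT3G30122, MAF4 and MAF5 were chosen after their values were seen.

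Of the 5 calls, 4 were higher and 1 was lower, with adjusted p of 4.27e-07 for HEI10, 9.88e-05 for MRD1, 0.0017 for AT3G30122, 0.00392 for MAF4 and 0.000561 for AT5G35935 in edgeR's quasi-likelihood test. MAF5 had adjusted p = 0.0517 (0.000442 to 0.3 over the alternatives, edgeR and DESeq2). With the replicate number as a block 10 genes were called, and DESeq2 called 8. All 5 calls lay outside the 23 lists. Camera called the jasmonate list as higher and the heat shock list as lower (adjusted p = 0.0244 for both; adjusted p = 0.853 with an estimated correlation). Between the mutants, 1 gene was called under ozone in both, AT5G35935, in opposite directions, where independent lists would share 0.267 and 20 simulations of unchanged mutants against the same Col-0 libraries gave 0. In control 2 genes were called in both, SADHU3-2 in the same direction and AT5G35935 in opposite ones, against 0.00125 for independent lists and 0 in the simulations. The simulated libraries were drawn gene by gene without the pairing by number, so their 0 does not gauge the overlap that shared Col-0 libraries could give. With separate pairs of Col-0 libraries for each mutant, chosen in 6 ways, 0 genes were called in both in control and 1 to 6 under ozone, AT5G35935 always among them.

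The ozone response itself differed between wrky25 wrky33-labelled rosettes and Col-0 in a set of genes. RHA1A (AT4G11370), a RING-H2 ubiquitin ligase, rose from 1.53 ± 0.511 to 94.5 ± 14.2 CPM (SD, n = 4) in Col-0 and from 1.00 ± 0.191 to 9.60 ± 2.00 CPM (SD, n = 3) in the double mutant, a difference of log2 responses of −2.69 ± 0.33 (SE). AT2G38870, a protease inhibitor of the PR-6 family, rose from 20 ± 3.35 to 219.8 ± 40.2 CPM in Col-0 and stood at 22.9 ± 5.18 and 41.7 ± 7.78 CPM in the double mutant (−2.59 ± 0.30). PRS3 (AT1G10700), a phosphoribosyl diphosphate synthase, went from 28.6 ± 5.0 to 116.7 ± 30.2 CPM in Col-0 and had 32.3 ± 2.74 and 28.8 ± 2.47 CPM in the double mutant (−2.20 ± 0.25). BGLU45 (−3.78 ± 0.64), GSTU10 (−2.32 ± 0.30), the transporter ABCG31 (−2.23 ± 0.42) and the exocyst subunit SEC3B (−2.19 ± 0.36) also responded less. CML41 (2.47 ± 0.50), DIP2 (2.33 ± 0.55), WRKY25 (2.27 ± 0.36), AT1G58225 (1.98 ± 0.44) and the extensin EXT4 (1.90 ± 0.41), which reached 295.4 ± 40.4 CPM in the double mutant and 99.0 ± 30.1 CPM in Col-0, responded more. In Col-0, ozone replicate 4 of EXT4 stood apart at 53.9 CPM, against 112 to 115 CPM, and control replicate 4 of DIP2 at 3.28 CPM, against 0.652 to 0.832 CPM.

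A difference of response was called for 191 genes, 53 higher and 138 lower in wrky25 wrky33-labelled libraries (edgeR quasi-likelihood test), with adjusted p of 0.000394 for RHA1A, 0.000277 for AT2G38870, 0.000156 for PRS3, 0.00686 for BGLU45, 0.0215 for CML41 and 0.0491 for DIP2. Of the 138, 128 had risen in Col-0, and 85 of those were called higher in the double mutant too. Under ozone 186 of the 191 were also called between the genotypes in the same direction. With the replicate number as a block 618 genes were called, 278 higher and 340 lower, all 191 among them, and with the block within each treatment 1023 were higher and 680 lower. DESeq2 called 363 and only the compared groups 113. Leaving out 1 library moved the count beyond 1.5 times in 9 of 14 cases. It was 121 and 110 without Col-0 control replicates 2 and 3, 96 and 121 without Col-0 ozone replicates 2 and 3, 110, 101 and 76 without wrky25 wrky33 control replicates 1, 2 and 3, and 120 and 84 without wrky25 wrky33 ozone replicates 2 and 3.

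**Figure D5:**
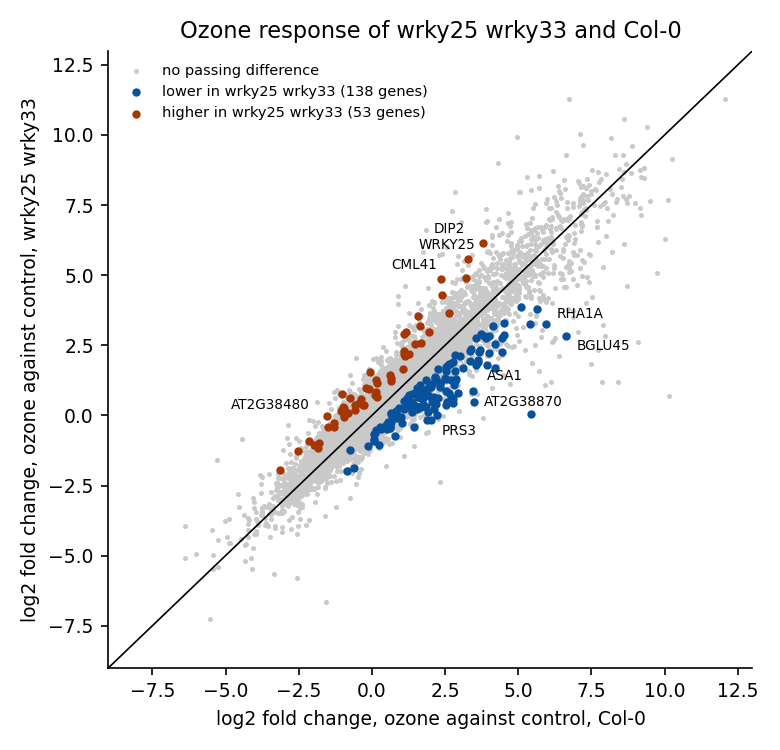
Log2 fold change under ozone in Col-0 (horizontal) and wrky25 wrky33 (vertical) for each gene tested, with the line of equal responses, grey points for genes without a passing difference and coloured points for those with one. The signed log2 response was lower in wrky25 wrky33 for 138 genes (blue) and higher for 53 (red).

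In the lists, 3 of 20 genes of tryptophan, camalexin and indole glucosinolate synthesis responded less, and 4 adjusted over the list alone. The 3 were ASA1 (−1.76 ± 0.27, adjusted p = 0.00314, edgeR) and ASB1 (−1.14 ± 0.21, adjusted p = 0.0124, edgeR) of anthranilate synthase and TSA1 (−1.25 ± 0.28, adjusted p = 0.0419, edgeR) of tryptophan synthase. With RLE or upper-quartile factors 2 members responded less, and with DESeq2 4. The list had adjusted p = 2.18e-05 with camera and adjusted p = 0.505 with an estimated correlation. In pattern-triggered immunity PUB23 (−2.18 ± 0.47) and the Pep receptor PEPR1 (−0.78 ± 0.16) responded less, 2 of 24 genes and 3 adjusted over the list alone (camera adjusted p = 0.056). The ethylene synthesis gene ACO4 (−1.17 ± 0.25) responded less and the sulfotransferase SOT12 (0.99 ± 0.18) more, and the kinase CRK22 fell more, by 1.97 in the double mutant and 0.85 in Col-0 (−1.13 ± 0.20). Camera also called the salicylic acid list as higher (adjusted p = 0.0116; adjusted p = 0.893 with an estimated correlation); its members were all outside the 191 genes.

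For wrky75-labelled rosettes no gene had a passing difference of ozone response from Col-0. WRKY25, WRKY33 and WRKY75 differed by 0.50, −0.69 and −0.28 on the log2 scale (adjusted p = 1 for each, edgeR). The count was 0 with edgeR's quasi-likelihood test, the smallest adjusted p was 0.141, and DESeq2 called 2 genes. Of 19954 genes tested, 349 had an unadjusted p under 0.05 in edgeR, fewer than the share of 0.05 that chance alone would give. With the block of the replicate number within each treatment 1236 were under 0.05 unadjusted, and 0 were called. Camera called the glutathione S-transferase, mitochondrial retrograde and salicylic acid lists as higher and the photosynthesis list as lower (adjusted p = 0.00197 for each), and the cysteine-rich receptor-like kinases as higher (adjusted p = 0.0205). With an estimated correlation adjusted p = 0.635 for the lowest and adjusted p = 0.982 for the highest of these 5 lists.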

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

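The tests of a uniformly weaker response, of replicate numbers, of scaling, of the response against that of wrky75, of the control calls in the ozone libraries alone, of the genes beside WRKY25 and WRKY33 and of the genes near WRKY75 were chosen after the results were seen, whereas the comparison with wrky75 under ozone and the other splits of the libraries were set before.

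The ozone response differed by a test of the difference itself for 191 genes between wrky25 wrky33-labelled libraries and Col-0. Among the genes named, 18 had a lower signed log2 response, with differences of log2 responses of −3.78 for BGLU45, −2.69 for RHA1A, −2.59 for AT2G38870, −2.32 for GSTU10, −2.23 for ABCG31, −2.20 for PRS3, −2.19 for SEC3B, −2.18 for PUB23, −1.76 for ASA1, −1.58 for ALDH2C4, −1.34 for AAT, −1.25 for TSA1, −1.17 for ACO4, −1.14 for ASB1, −1.13 for CRK22, −1.05 for AT4G36220, −0.92 for DHS1 and −0.78 for PEPR1. Of these CRK22 fell in both lines, and by more in wrky25 wrky33. The 7 with a higher signed response were CML41 (2.47), DIP2 (2.33), WRKY25 (2.27), AT1G58225 (1.98), EXT4 (1.90), AT2G38480 (1.52), which fell in Col-0 and changed by −0.01 in wrky25 wrky33, and SOT12 (0.99). Of 100 splits of the Col-0 and wrky25 wrky33 libraries drawn within each treatment, 3 gave as many calls, the real one included, and the highest of the others was 254. Over all 100 splits the share is under 0.05, but the libraries pair by number, and the 2 other splits that parted as many pairs, with at most 2 calls, are too few to exclude chance.

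The smaller induction of 128 genes in wrky25 wrky33-labelled rosettes was weighed first. A weaker ozone response of all genes alike was argued against, because 90 of the 128 were still lower after the Col-0 response was multiplied by 0.969, the median ratio of the induced genes. With a block of the replicate number within each treatment 128 remained lower. Each mutant library has a same-numbered Col-0 library in its treatment, so the block could hardly remove a difference between genotypes. It therefore does not decide whether differences between replicate numbers play a part. The scaling of the libraries was argued against, since at least 102 remained lower under RLE, upper-quartile or DESeq2 scaling. Nor did the pattern rest on the Col-0 libraries alone, since all 128 were lower than in wrky75 under ozone, and had a lower response than wrky75, by 50% or more of their difference from Col-0, with 72 passing for the response (edgeR; median difference −1.11, and −1.15 from Col-0). A difference in regulation between the lines may explain it, as a hypothesis found and tested on the same data, and whether the lesions named in the label cause it was not tested.

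The genes beside WRKY25 and WRKY33 were higher in wrky25 wrky33-labelled libraries. Reads of the adjacent WRKY gene counted to its neighbour were argued against as the whole cause, because under ozone, in the mutant, ATCHX13 fell by 2.37 ± 0.23 on the log2 scale and AT2G38480 changed by −0.01. AT2G38480 fell by 1.53 in Col-0, and its excess over Col-0 grew 1.7-fold while WRKY33 rose 24.6-fold, so a part from such reads stays open for it. A sequence change at the mutated loci may be another cause and stays open, since the 4 flanking genes were singled out after 2 of them were seen among the 5 calls in control, and the exact hypergeometric p = 3.01e-07 only restates that. The sequence at these loci was not analysed here.

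The genes called between wrky75-labelled libraries and Col-0 recurred with and without ozone. A difference between the lines that does not need ozone may account for them, since 4 of the 6 genes called in either treatment were called in both in the same direction, where independent lists would share 0.00125. Of the called genes 0 lay within 1 Mb of WRKY75, and the nearest on chromosome 5 was 9.9 Mb away. A sequence change near WRKY75 stays open all the same, since it need not alter the transcripts of its neighbours. Which sequence differences the lines carry was not tested.

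Other splits of the same libraries were counted for the remaining comparisons. For ozone against control in Col-0, 1 of 35 splits gave as many calls as the 13907 of the real split, and the highest of the others was 2956. That share is under 0.05 and the smallest that 35 splits allow, so chance is argued against but not excluded. The splits of wrky25 wrky33 (12980 calls) and of wrky75 (13594 calls) by ozone number 10 each, too few for a share under 0.05. In each, 1 split reached the real count and the highest of the others was 0. For wrky25 wrky33 against Col-0 under ozone 1 of 35 splits reached 1064, and the highest of the others was 597, but only 7 other splits part as many same-numbered pairs as the real one, too few for a share under 0.05. In control, 2 of 35 splits gave 5 or more calls for wrky25 wrky33 and 4 of 35 for wrky75, with 43 and 161 as the highest of the others, so the splits do not exclude chance for these counts. The splits with 43 and 161 calls parted 0 and 1 same-numbered pairs, where the real ones parted 3. In fits of the ozone libraries alone 4 of the 5 genes for wrky25 wrky33 and 2 of the 5 for wrky75 were called again in the same direction, where independent lists would share 0.183 and 0.00104 (exact hypergeometric p = 8.65e-06 and 3.22e-07). This argues against chance in the control libraries as the source of both sets of calls, and single genes stay open. Under ozone 4 of 35 splits gave 5 or more calls for wrky75, and the highest of the others, 3674, put Col-0 replicates 1 and 4 with wrky75 replicate 1. For the difference of responses in wrky75 the real count is 0, so all 100 splits reach it by definition and say nothing of chance, with 2778 as the highest of the others. Splits that call several times the real count point to a structure of the samples, and in wrky75 under ozone the split followed the replicate numbers. Among the splits that part as many pairs, the highest of the others was 0 for both mutants in control, and under ozone it was 449 for wrky25 wrky33 and 1 for wrky75.

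Single libraries stood apart in groups of 4, in Col-0 alone because the mutant groups hold 3. Of 314 such groups, 21 (6.7%) had a gap to the nearest library beyond Dixon's 95% critical value as a share of the range, and chance gives about 1 in 20. In Col-0 control, replicate 1 stood apart for WRKY33 (0.916; 14.8 against 23 to 23.8 CPM), UBQ10 (0.892) and SOT12 (0.83). Replicate 2 stood apart for PROPEP3 (1; a single count), GSTU4 (0.871; 5.16 against 1.71 to 2.16 CPM), PRR5 (0.878), ASB1 (0.849) and AT1G80820 (0.864). Replicate 3 stood apart for the total count (0.867), HSFA2 (0.841), IAA5 (0.921) and PHT1;4 (0.928; 5.58 against 2.86 to 3.06 CPM), and replicate 4 for DIP2 (0.932; 3.28 against 0.652 to 0.832 CPM). In Col-0 ozone, replicate 4 stood apart for EXPA8 (0.831; 6.21 against 2.38 to 3.03 CPM), CYP94B3 (0.898; 5.59 against 0.183 to 0.734 CPM), HEI10 (0.83), EXT4 (0.956; 53.9 against 112 to 115 CPM) and CSLG3 (0.83). Replicate 1 stood apart for CSLE1 (0.925; 147 against 186 to 189 CPM) and SAUR28 (1; a single count), and replicate 3 for the total count (0.909).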

How the results depend on the processing

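The block of the replicate number within each treatment and the fits with separate pairs of Col-0 libraries were chosen after the data were seen. The ozone counts within each genotype stayed within 1.5 times under all alternatives, and no called gene named in the text changed direction under any. Leaving out 1 library gave 12917 to 14030 calls in Col-0, 11783 to 12709 in wrky25 wrky33 and 12535 to 13486 in wrky75. For wrky25 wrky33 against Col-0 in control, with 5 calls, DESeq2 gave 16, only the groups compared 1, the block within treatment 53 and leaving out 1 library 1 to 7. For wrky75 in control, with 5, DESeq2 gave 19, the block within treatment 14 and leaving out 1 library 3 to 64. Under ozone wrky25 wrky33, with 1064, had 2394 with the replicate block, 4672 with the block within treatment, 707 with only the groups compared and 583 to 1171 with 1 library left out. For wrky75 under ozone, with 5, DESeq2 gave 8, the replicate block 10, the block within treatment 17 and leaving out 1 library 5 to 7. For the difference of responses of wrky25 wrky33, with 191, DESeq2 gave 363, the replicate block 618, the block within treatment 1703, only the groups compared 113 and leaving out 1 library 76 to 226. For that of wrky75 edgeR called 0, with 349 at an unadjusted p under 0.05, fewer than chance alone would give. There DESeq2 gave 2 and leaving out 1 library 0. The cause was not tested, except that leaving out libraries or groups lowers the number of samples in the fit. In simulated counts with few genes changed, unchanged genes made up 10.5% to 19.8% of DESeq2's calls over the comparisons. For edgeR without a block the shares were 2.4% to 9.8%, so DESeq2's larger counts may hold more false calls.

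Same-numbered libraries paired between genotypes within a treatment, and the block changed the WRKY25 call in control and under ozone (adjusted p = 0.139 to 0.00319, edgeR) and the counts above. The balance turned as well, with 311 higher and 753 lower for wrky25 wrky33 under ozone but 2444 and 2228 with the block within treatment. In that block Col-0 replicate 4 is the only library of its number in its treatment, so it does not bear on the mutant. Without a block, Col-0 replicates 1 to 3 only gave 558 higher and 823 lower, and leaving out Col-0 ozone replicate 4 gave 448 and 723. The balance thus moved part of the way without that library, and the cause of the rest was not tested. Between ozone and control within a genotype the libraries share only a number, since the lowest correlations were −0.007 in Col-0, −0.081 in wrky25 wrky33 and −0.012 in wrky75, and 2, 1 and 2 of 3 numbers matched best. The block gave 14959, 14229 and 14771 calls there. Of 207 list tests camera called 88, and 1 held with an estimated correlation. Fry called 64, 50 of them shared, camera with the replicate block 85 (79 shared), with RLE factors 83 (82) and with Col-0 replicates 1 to 3 78 (71). Among 230 called results of named genes, 226 kept their call with DESeq2, 225 without a filter on low counts, 229 with the block and 221 with Col-0 replicates 1 to 3. Only the groups compared kept 212 of 229. The lowest share kept was 29 of 43, without wrky25 wrky33 control replicate 3, and 65 of 93 were kept without its ozone replicate 3. In simulated counts of this depth, with few genes changed, edgeR called genes changed 1.5-fold in 0% to 33.3% of cases over the comparisons, and these shares do not carry over to comparisons with many calls.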

Other observations

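The gene families, the added lists and the levels near the mutated loci in this part were chosen after the data were seen, and the tests of promoter elements and of the aromatic and phenylpropanoid lists were set before their results were known. Other gene families also moved under ozone in Col-0, where 33.3% of all genes tested rose and 36.4% fell. Of 14 families tested by Fisher's exact test with Benjamini-Hochberg adjustment over 28 tests, wall-associated kinases rose in 7 of 8 members (adjusted p = 0.0143), with WAKL10 at a log2 fold change of 7.70 ± 0.32 and WAK3 at 4.66 ± 0.44 (SE). Receptor-like proteins rose in 28 of 49 (adjusted p = 0.00511), with RLP21 at 5.45 ± 0.45 and RLP52 at 5.06, and calmodulin-like proteins in 6 of 7 (adjusted p = 0.027), with CML38 at 5.43 and CML42 at 4.03. NAC factors rose in 26 of 52 (adjusted p = 0.04) and fell in 5 (fewer than other genes, adjusted p = 0.000477), with NAC042 at 4.99. Aquaporins fell in 17 of 22 (adjusted p = 0.00223), PIP2A by 2.80 ± 0.23 and PIP2E by 2.06 ± 0.19, SAUR genes in 12 of 15 (adjusted p = 0.00511), SAUR20 by 5.41 ± 0.47, and cellulose synthases and their relatives in 17 of 26 (adjusted p = 0.0162), CSLG3 by 2.84, although CSLE1 rose by 3.49. With upper-quartile factors the counts were 7 of 8, 23 of 49, 5 of 7, 23 of 52, 17 of 22, 12 of 15 and 18 of 26 in the same order. Glucosyltransferases, cytochromes P450, ABCG transporters, MYB factors, U-box ligases, B-box factors and tubulins did not pass in either direction. Fisher's test takes the members of a family as independent, although they could share reads, and correlation between them was not estimated. With families chosen after the data were seen, these p-values describe the counts and do not test a family.

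Genes that supply aromatic amino acids and phenylpropanoids rose under ozone in Col-0, in 13 of 20 and 13 of 16 measured members, with 2 and 1 lower. AT1G80820, a cinnamoyl-CoA reductase, stood at 5.38 ± 0.24 on the log2 scale, ADT4 at 3.19 ± 0.19, ALDH2C4 at 2.87 ± 0.11 and AAT at 1.74 ± 0.12, and ATCAD4 fell by 1.29 ± 0.12 and CM1 by 0.93 ± 0.12. Under ozone wrky25 wrky33-labelled libraries were lower than Col-0 in 4 and 3 of these members, with ALDH2C4 at −1.79 ± 0.12 (adjusted p = 3.48e-08, edgeR), AAT at −1.27 ± 0.13 (7.06e-06), AT4G36220, a ferulate hydroxylase, at −1.17 ± 0.11 (1.99e-06) and DHS1 at −0.85 ± 0.15 (0.00204). AAT, AT4G36220 and ALDH2C4 had been seen before the lists were made. Among ozone-induced genes, 4 of 23 members not named before were lower in wrky25 wrky33, against 684 of 6609 other genes, an odds ratio of 1.82 with a 95% interval of 0.45 to 5.51 (2-sided Fisher's exact p = 0.291). A bound on p alone was too wide a prediction, since 23 members leave an interval that holds both no difference and a large one, and the question stays open.

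The hypothesis that genes lower in wrky25 wrky33-labelled libraries under ozone carry more W-box elements, the sites WRKY factors bind, was tested on the 1000 bases upstream of ozone-induced genes. The 691 lower genes had 1.564 ± 1.304 W-boxes (SD) and at least 1 in 76.8%, against 1.362 ± 1.29 and 71.2% in 5831 other induced genes. Draws matched by induction and level in Col-0, from the lower and the other genes together, averaged 1.599. The one-sided permutation p was 0.777 with 100000 resamples, so no excess was detected once induction was matched. Such matching also removes any excess that goes with induction itself, which this test therefore cannot address. The reversed element, a check of base composition, gave a permutation p = 0.63. For the 104 higher genes the mean was 1.673 against 1.445 in draws matched in the same way (permutation p = 0.0434, one-sided, not adjusted over the tests), and the reversed element gave a permutation p = 0.295.

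Under ozone ATCHX13 stood at 2.71 ± 0.452 CPM (SD, n = 3) in wrky25 wrky33-labelled libraries, where Col-0 had 2 counts in 4 libraries (edgeR adjusted p = 1.89e-06). MAF5 in wrky25 wrky33-labelled libraries had a mean of 4.50 ± 5.35 CPM in control and 2.95 ± 4.09 CPM under ozone (SD, n = 3), an SD above the mean in both.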
